A study of Mus musculus with 44 samples.

How the data were processed

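Small RNA was profiled in hypothalamus samples of 44 mice, with RNA from the miRNeasy kit (integrity number above 8.4 per the labels) and libraries made from 200 ng with the NEBNext small RNA kit and read on a NextSeq 500. The authors deposited 2 tables of raw read counts, one per mature miRNA and one per tRF, and each deposited value is an unnormalised count. The labels list FastQC and give no version. Adapter trimming, aligner, miRNA release and genome build are not stated, and the choices behind the counts could not be checked. All 44 columns of each table were matched to the labels by group and replicate number, and 0 columns belonged to other samples.

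The miRNA table lists 1978 mature miRNAs, of which 432 have 0 counts throughout. There are 17051 tRFs of 16 to 50 nt, with names of the MINTmap type. Of 567 miRNAs with at least 440 counts in all, 10 have the same counts as another in every library, and let-7a-1-3p and let-7c-2-3p differ in 2 libraries only, by 1 count; how shared reads were assigned is not stated. Of the 17051 tRFs 4689, with 60% of counts, list a tRNA location outside the mouse chromosomes, and the reference used is not stated. The 88 tRFs labelled mitochondrial hold 196 of 4569025 counts, and 0 tRF sequences occur in the 22 mouse mitochondrial tRNAs of the annotation. The amino acid and anticodon given for a tRF are those of the table's own reference, and no tRF coordinates are given. miRNA genes were placed on GRCm38 with GENCODE vM21.

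Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Features were kept by filterByExpr (minimum count 10, minimum total 15), scaled by TMM within each table, and tested by quasi-likelihood F tests with Benjamini-Hochberg adjustment at 0.05. AM132 was compared with AM608 over 32 libraries with batch as a term. The RCD comparisons used the 20 libraries of batch 2 in 1 fit of 3 groups, since elsewhere group and batch coincide. Fold changes are log2, AM132 or AM608 minus the group named after it, and their SE is the absolute fold change divided by the square root of F. Per-library log2 CPM values used TMM over all 44 libraries and a prior count of 2. The agreement of direction is the number of libraries on the side of the fold change from the other group's mean in the same batch.

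Single values were compared by 2-sided permutation tests, with 100000 resamples within batch for 16 against 16 libraries and exact enumeration within a batch. A batch of 4 against 4 libraries has 70 splits and one of 8 against 8 has 12870. The interval for a single library is Wilson's at 95%, and it covers counting error only, since reads without molecular identifiers are not independent molecules. The depth of 38619 to 221358 counts per library for tRFs sets much wider counting error than the 3020192 to 5997234 for miRNAs.

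Before the data were examined, 17 miRNA lists were fixed: the cluster of miR-132 and miR-212, the miR-194 family, neuronal, energy-balance, lipid-metabolism, oligodendrocyte, astrocyte, myeloid, endothelial and mural, erythroid, pituitary, choroid plexus and ciliated-cell, muscle and Hox-linked lists, the Dlk1-Dio3 cluster, the let-7 family and the miR-17/92 clusters. The lists overlap, with miR-7a-5p, for example, in the neuronal, energy-balance and pituitary lists, and most members are expressed in hypothalamus too. tRFs were grouped by amino acid and by fragment type. Sets of at least 3 tested members were tested by camera on log2 CPM with a preset correlation of 0.01, again with an estimated correlation, and by fry, which tests a set against no change and not against the other features. The rule for named features was also fixed: those past the test with a mean of at least 10 CPM, up to 10 per direction; the 5 of smallest p where fewer than 5 pass; all tested members of the first 2 lists; the 2 of smallest p of each other list described; and the 4 lysine fragments of smallest p. Other features were named after their values were seen: miR-204-5p, miR-1298-5p, miR-206-3p, tRF-31-PW5SVP9N15WV0, the long LysCTT fragments, and the miRNAs given for single libraries.

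The alternatives were RLE scaling, DESeq2 1.42.0, no filter, at least 10 CPM in 16 (or, against RCD, 4) libraries, no batch term, each batch alone, TMM over both tables, all 44 libraries and each RCD library of batch 2 left out. Within each group no library duplicated another, as the closest pair had a chi-square per degree of freedom of 5.02. After the data were seen, fits without AM132 6, without AM132 5, AM132 6 and AM608 5, without fragments of 47 to 50 nt, and without AM132 8, AM132 12, AM608 8 and RCD 10 (few lysine 5'-half fragments of 35 nt) were added.

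The fits were tested on simulated data with the same design and the spread of each feature, in which 200 features were changed. A log2 change of 1 was recovered for 98.4% of miRNAs between AM132 and AM608, 83.6% between AM608 and RCD, and 90.9% between AM132 and RCD; for tRFs it was 79.7%, 21.5% and 34.4%. A change of 0.5 was recovered for 92.1%, 56.7% and 45.5% of miRNAs and 26.7%, 1.56% and 4.55% of tRFs. False calls were 1.56% to 4.24% of calls. With 200 features changed and 440 to 594 tested, a large share was changed, which loosens the adjusted threshold. The recovered shares may therefore be higher than they would be in the real data, where few features passed. Of 20 unchanged sets per simulation, camera with the preset correlation gave an unadjusted p under 0.05 to 4 for tRFs between AM132 and AM608 and to 0 or 1 in the other 5. Each feature was drawn independently, so correlation between features and libraries that stand apart were not simulated. In the real data between AM132 and AM608 the estimated correlation was 0.303 for lysine fragments and 0.306 for 5'-halves. The false calls and unchanged sets therefore do not show how the tests behave with such correlation. Sequence comparisons and plots used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.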

Results

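The deposited tables count 2 classes of small RNA in the mouse hypothalamus, the brain region that governs feeding and energy use. The first class is the mature miRNAs, and the other is tRNA fragments (tRFs), pieces cut from transfer RNAs. The 44 C57Bl/6J libraries fall into 3 groups. AM132 (16 libraries) came from obese mice given a locked nucleic acid (LNA) oligonucleotide of 16 nt against miR-132, and AM608 (16 libraries) from obese mice given one of 15 nt against the primate miR-608, the control. RCD (12 libraries) came from lean mice on regular chow. The oligonucleotides were given at 3.3 mg/kg on 3 days, after 11 weeks of diet, and tissue was taken 7 days later. The labels do not describe the RCD mice as injected, so obesity and injection cannot be told apart in any comparison with RCD.

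The labels name 4 batches. Batch 1 and batch 3 each held 4 AM132 and 4 AM608 libraries, batch 2 held 8 AM132, 8 AM608 and 4 RCD libraries, and batch 4 held 8 RCD libraries alone. The miRNA table gave 3020192 to 5997234 counts per library (median 3996700), and the tRF table gave 38619 to 221358 (median 99504). Brain-abundant miRNAs led the miRNA counts: miR-9-5p took 11% of them, miR-128-3p 10.7%, miR-26a-5p 6.78% and miR-7a-5p 6.69%. Fragments of lysine tRNAs took 45.7% of tRF counts and fragments of glutamate tRNAs 31.3%. By fragment type, internal fragments (i-tRF) took 35.7%, 5'-tRFs 33.8%, 3'-tRFs 4.88% and 3'-halves 1.06%, and 5'-halves held 1125003 of 4569025 counts. Batch set most of the miRNA profile: the first principal component held 57.6% of the miRNA variance, and 97.2% of its variance lay between batches. Within RCD, 161 of 598 miRNAs were higher and 170 lower in batch 4 than in batch 2. RCD was therefore compared within batch 2 only.

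The comparison of AM132 with AM608 asks what the oligonucleotide against miR-132 changed in the obese hypothalamus. Its target, miR-132-3p, an activity-dependent neuronal miRNA, was lower in AM132. The mean was 9.29 ± 1.15 log2 CPM in AM132 and 9.86 ± 0.53 in AM608 (SD, n = 16 each), a difference of -0.57 (permutation within batch, 2-sided p = 5e-05). It was -0.35 without AM132 6 (permutation p = 0.00122) and -0.30 without the 3 libraries rich in miRNAs of other tissue, AM132 5, AM132 6 and AM608 5 (permutation p = 0.00571). Within batches the difference was -0.18 in batch 1 (n = 4 and 4, exact permutation p = 0.2, adjusted over the 3 batches 0.257), -0.95 in batch 2 (n = 8 and 8, exact permutation p = 0.000155, adjusted 0.000465) and -0.20 in batch 3 (n = 4 and 4, exact permutation p = 0.257, adjusted 0.257). In batch 2 all 8 AM132 libraries (highest 9.06) lay below all 8 AM608 libraries (lowest 9.07). Only batch 2 passed on its own. The edgeR test of whether the effect differed between batches gave p = 0.188 for miR-132-3p (adjusted over 559 miRNAs 0.945). That does not show that the batches were alike. The lowest library was AM132 6, with 253 of 4063385 counts, or 62.3 CPM before scaling (Wilson 95% interval 55 to 70.4); without it the batch 2 difference was -0.61 (n = 7 and 8, exact permutation p = 0.000311).

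The other arm of the same hairpin, miR-132-5p, differed by -0.07 ± 0.07 (log2 fold change ± SE), with an adjusted p of 0.955 in edgeR. The log2 ratio of miR-132-3p to miR-132-5p was -1.32 ± 0.73 in AM132 and -0.84 ± 0.23 in AM608 (SD, n = 16 each; difference -0.48, permutation p = 0.00065), and it differed by -0.31 without AM132 6 (permutation p = 0.00143) and by -0.27 without the 3 libraries (permutation p = 0.00488). Within batches this ratio differed by -0.28 in batch 1 (exact permutation p = 0.0286, adjusted over the 3 batches 0.0429), by -0.89 in batch 2 (exact permutation p = 0.000155, adjusted 0.000465; -0.58 without AM132 6, exact permutation p = 0.000155) and by 0.15 in batch 3 (exact permutation p = 0.314). In the genome-wide fit miR-132-3p had a log2 fold change of -0.46 ± 0.16 and was lower in 14 of 16 AM132 libraries, but its adjusted p over 559 miRNAs was 0.593. Adjusted over the list alone, the 4 arms of the cluster of miR-132 and miR-212 gave 1 call, miR-132-3p (adjusted p = 0.0255). Its neighbours miR-212-3p (-0.07 ± 0.08) and miR-212-5p (0.00 ± 0.08) did not pass. Mir132 lies on chromosome 11 of GRCm38 at 75173682 to 75173747 and Mir212 at 75173388 to 75173478, both on the plus strand in an intron of the noncoding gene 1700016P03Rik. Read counts do not separate loss of a miRNA from its masking by bound oligonucleotide during library preparation.

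**Figure D1:**
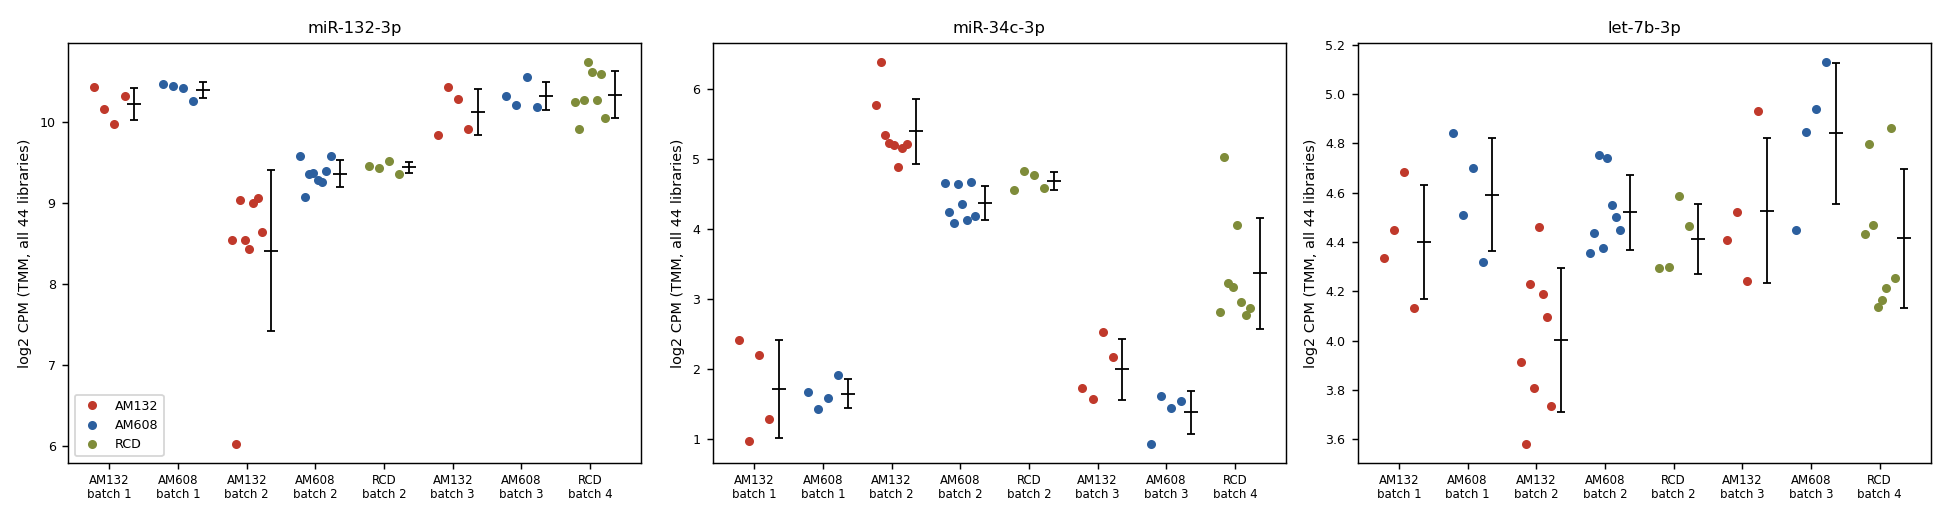
Each point is a library, placed by batch and group, with log2 CPM on the vertical axis for miR-132-3p (left), miR-34c-3p (middle) and let-7b-3p (right); the black marks are the mean and SD. In batch 2 the miR-132-3p values of AM132 run from 6.03 to 9.06 and those of AM608 from 9.07 to 9.57, while miR-34c-3p runs from 4.89 to 6.38 in AM132 and from 4.09 to 4.67 in AM608.

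Over all 559 tested miRNAs 1 rose and 1 fell in AM132, in edgeR and in DESeq2 alike, and 23 had an unadjusted p under 0.05 in edgeR. miR-34c-3p, from a p53-responsive miRNA family that is abundant in ciliated cells, rose by a log2 fold change of 0.91 ± 0.16 (adjusted p = 0.00169; higher in 14 of 16 AM132 libraries). It averaged 23.8 ± 23.9 CPM in AM132 and 11.5 ± 9.74 in AM608 (SD, n = 16 each). In batches 1 and 3 it had only 6 to 20 counts per library. The more abundant arm of the hairpin, miR-34c-5p, did not follow it in batch 2. There the edgeR log2 fold change was 1.12 ± 0.19 for miR-34c-3p and 0.12 ± 0.07 for miR-34c-5p. In batches 1 and 3 miR-34c-5p stood at 0.40 ± 0.22 and 0.47 ± 0.24. let-7b-3p, the minor arm of a let-7 hairpin, fell with a log2 fold change of -0.38 ± 0.09 (adjusted p = 0.0492; lower in 14 of 16), averaging 18.9 ± 4.79 CPM in AM132 and 24.4 ± 4.35 in AM608. In log2 CPM, miR-34c-3p differed by 0.07 in batch 1, 1.03 in batch 2 and 0.62 in batch 3 (exact permutation p = 0.886, 0.000155 and 0.0571, adjusted over the 3 batches 0.886, 0.000465 and 0.0856). let-7b-3p differed by -0.19, -0.52 and -0.32 (exact permutation p = 0.229, 0.000777 and 0.2, adjusted 0.229, 0.00233 and 0.229). Mir34c lies on chromosome 9 at 51103034 to 51103110, minus strand, opposite an intron of Btg4, and Mirlet7b on chromosome 15 at 85707319 to 85707403, plus strand, in an exon of Lncppara. The let-7b-3p call ended in several fits: its adjusted p was 0.164 with no low-count filter, 0.106 with scaling over both tables, 0.0509 without AM132 6 and 0.113 without the 3 libraries rich in miRNAs of other tissue. Without AM132 6 miR-132-3p passed instead (log2 fold change -0.37 ± 0.08, adjusted p = 0.0152). It did not pass without the 3 libraries, where miR-34c-3p was the only call.

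Of the miRNAs next in rank, none passed: miR-101b-3p (0.11 ± 0.03), miR-101a-3p (0.13 ± 0.04) and miR-879-5p (0.15 ± 0.05) had adjusted p values of 0.496, 0.569 and 0.593. miR-194-5p, which the study's title names, was level between the groups, at 295 ± 29.9 CPM in AM132 and 303 ± 32.55 in AM608 (log2 fold change -0.04 ± 0.05, adjusted p = 0.983). Its family list gave 0 calls adjusted over the list alone among 3 tested members, with miR-192-5p at 0.14 ± 0.06 and miR-215-5p at -0.15 ± 0.13. The study chose miR-194, so its value is not independent evidence. Mir194-1 lies on chromosome 1 at 185313319 to 185313385 in an intron of 2010103J01Rik, with Iars2 on the opposite strand, and Mir194-2 on chromosome 19 at 6264643 to 6264728.

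The cell type and pathway lists held few calls. The choroid plexus and ciliated-cell list had 12 tested members, 9 of them with a positive fold change. Over all miRNAs 1 of them passed (miR-34c-3p), and adjusted over the list alone 2 rose, miR-34c-3p and miR-34c-5p (0.27 ± 0.10), and 1 fell, miR-204-5p (-0.16 ± 0.06), an abundant choroid plexus miRNA. Without AM132 6, whose mean for this list was 7.66 log2(CPM + 1) against 5.38 to 6.28 in the other AM132 libraries of batch 2, the 2 miR-34c arms passed adjusted over the list alone and miR-204-5p did not, and the list's median moved from 0.20 to -0.02. Without the 3 libraries rich in miRNAs of other tissue, AM132 6 among them, the calls were the same but the median was 0.18. The Hox-linked list had 2 tested members and 1 that rose adjusted over the list alone, miR-10a-5p (0.26 ± 0.10), a call that ended without AM132 6. The muscle list had 3 tested members and 0 calls; miR-1a-3p stood at 0.68 ± 0.28 and miR-133a-3p at 0.77 ± 0.35, and AM132 6 alone had a list mean of 6.64 against 3.77 to 4.20 in the other 7; the list median moved from 0.68 to 0.16 without AM132 6. The pituitary list had 8 tested members and 0 calls, with miR-375-3p at -1.47 ± 0.78 and miR-7a-2-3p at -0.22 ± 0.10, and AM608 5 had a list mean of 10.43 against 5.46 to 7.22 in the other 7 AM608 libraries of batch 2, while AM132 6 had 10.25 against 5.52 to 8.14 in the other 7 of AM132; the list median was 0.31, -0.415 without AM132 6 and 0.14 without the 3 libraries.

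**Figure D2:**
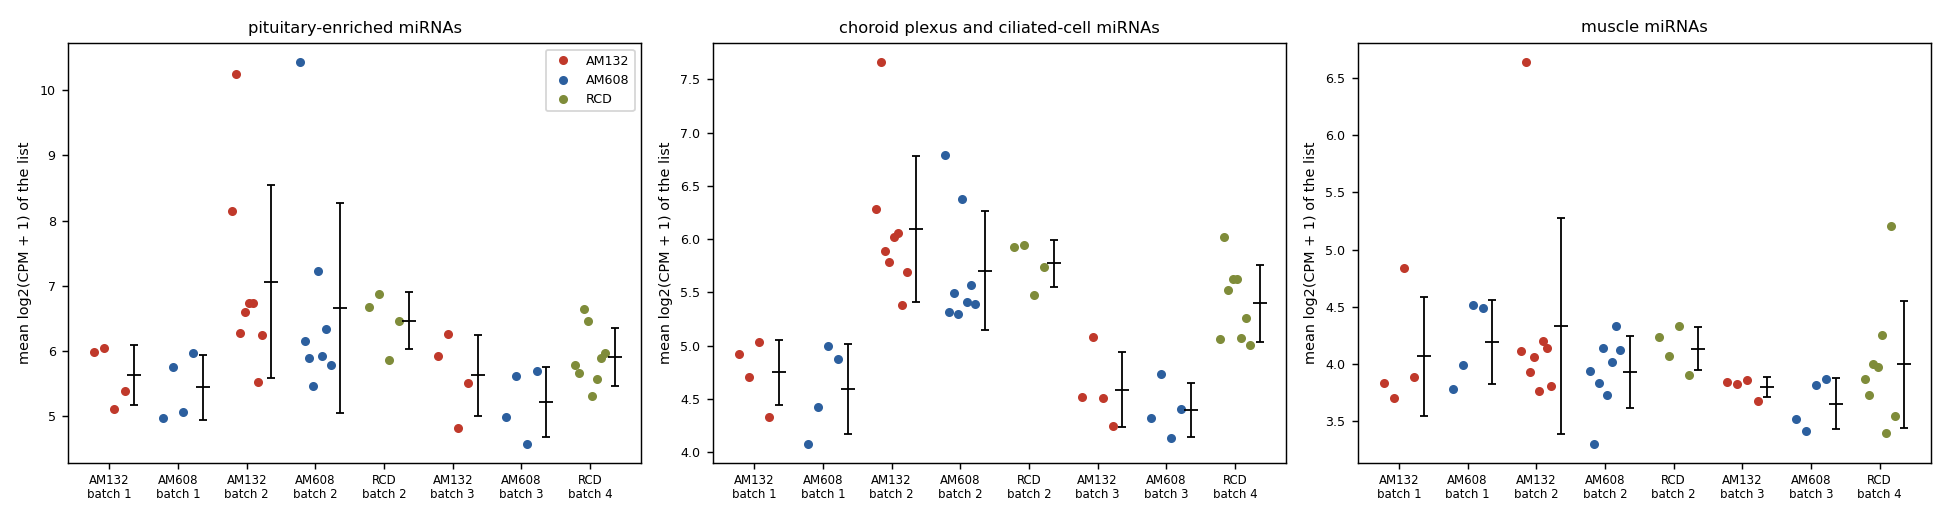
Each point is a library, placed by batch and group, with the mean log2(CPM + 1) of the pituitary (left), choroid plexus and ciliated-cell (middle) and muscle (right) lists on the vertical axis; black marks are the mean and SD. AM608 5 reaches 10.43 and AM132 6 reaches 10.25 for the pituitary list, and AM132 6 reaches 6.64 for the muscle list.

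The remaining lists gave 0 calls, over all miRNAs and adjusted over the list alone. They were the neuronal list (18 tested; miR-129-1-3p -0.13 ± 0.09, miR-138-5p -0.10 ± 0.08), energy balance (14; miR-200b-3p 1.33 ± 0.80, miR-200a-3p 1.18 ± 0.77, the latter at 6874 CPM in AM132 6, 2025 in AM608 5 and at most 305 in the other 42 libraries) and lipid metabolism (15; miR-148a-3p 0.56 ± 0.29, at 141100 CPM in AM132 6 and at most 19290 in the other 43 libraries, miR-27b-3p 0.14 ± 0.07). The glial lists were those of oligodendrocytes (5; miR-219a-2-3p 0.08 ± 0.21, miR-23a-3p 0.02 ± 0.09) and astrocytes (4; miR-29c-3p -0.07 ± 0.05, miR-29b-3p -0.03 ± 0.04). The vascular and blood lists were the myeloid (7; miR-150-5p -0.12 ± 0.07, miR-21a-5p 0.15 ± 0.10), endothelial and mural (7; miR-126a-5p -0.14 ± 0.06, miR-126a-3p -0.08 ± 0.05) and erythroid ones (5; miR-144-3p -0.06 ± 0.25, miR-486a-5p 0.03 ± 0.14). The genomic families were the imprinted Dlk1-Dio3 cluster (45; miR-376c-3p -0.17 ± 0.07, miR-667-3p -0.15 ± 0.07), the let-7 family (10; let-7g-5p 0.07 ± 0.04, let-7f-5p 0.04 ± 0.04) and the miR-17/92 clusters (10; miR-19a-3p -0.16 ± 0.17, miR-106b-5p 0.05 ± 0.08). As sets against all other miRNAs, the lowest adjusted p over 16 lists was 0.133, for the cluster of miR-132 and miR-212 (down) and the choroid plexus list (up); it was 0.831 with an estimated correlation. The signs of median, mean and set test differed for the miR-194 family (-0.04, -0.02, up), the endothelial and mural list (-0.03, 0.03, down), the erythroid list (0.03, 0.00, up) and the miR-17/92 clusters (0.03, 0.00, down).

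Among tRFs 0 of 494 passed between AM132 and AM608 in edgeR, 33 had an unadjusted p under 0.05, and DESeq2 called 0. The 4 fragments with the smallest p were all 5' pieces of the histidine tRNA HisGTG. They were tRF-31-6SXMSL73VL4YD (0.91 ± 0.25, higher in 15 of 16 AM132 libraries), tRF-32-6SXMSL73VL4YK (0.67 ± 0.20, 14 of 16), tRF-34-6SXMSL73VL4YHE (0.63 ± 0.19, 15 of 16) and tRF-32-XSXMSL73VL4YK (0.58 ± 0.18, 13 of 16). Their adjusted p values were 0.407, 0.407, 0.407 and 0.409. As 5' pieces of the same tRNA they overlap, so they are not 4 separate results. tRF-31-6SXMSL73VL4YD averaged 1030 ± 462 CPM in AM132 and 574 ± 294.6 in AM608, and its log2 fold change was 0.38 in batch 1, 1.41 in batch 2 and 0.70 in batch 3. The next was an internal GlyGCC fragment, tRF-30-J87383RPD9W1, at -0.73 ± 0.27 (adjusted p = 0.644). Of the 38 tested histidine fragments 21 were higher and 17 lower in AM132; their median log2 fold change was 0.08 and their mean -0.14, and 16 had an unadjusted p under 0.05 (set test up, adjusted p = 0.485 in camera).

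Lysine fragments, the group named in the study's title and so not independent evidence, had 112 tested members, 40 higher and 72 lower in AM132. Their median log2 fold change was -0.22, and 0 passed. The 4 with the smallest p were 2 5'-tRFs of LysTTT, tRF-25-PS5P4PW3FJ (0.59 ± 0.28) and tRF-22-PS5P4PW3H (0.43 ± 0.23), and 2 internal fragments of LysCTT, tRF-28-3JVIJMRPFQDS (-0.57 ± 0.30) and tRF-29-3JVIJMRPFQHX (-0.54 ± 0.31), each with an adjusted p of 0.644. As sets against all other tRFs, the 49 5'-halves (median 0.26, adjusted p = 3.71e-08) and the 97 5'-tRFs (median 0.16, adjusted p = 5.68e-05) were higher, and the 263 internal fragments (median -0.08, adjusted p = 2.19e-08) and the lysine fragments (adjusted p = 0.0156) were lower, all with a preset correlation. With an estimated correlation none of these 4 held (adjusted p = 0.447, 0.447, 0.0859 and 0.873).

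AM608 against RCD asks how obese mice given the control oligonucleotide differed from lean mice, within batch 2 (n = 8 and 4). Of 599 miRNAs 0 passed in edgeR, 30 had an unadjusted p under 0.05, and DESeq2 called 0. The smallest p belonged to miR-690 (-0.63 ± 0.17; 11.2 ± 2.46 CPM in AM608, 17.2 ± 4.22 in RCD), miR-187-3p (0.37 ± 0.11), miR-7688-5p (0.67 ± 0.15), miR-216b-5p (0.35 ± 0.11) and miR-103-3p (-0.15 ± 0.05), a regulator of insulin sensitivity, each with an adjusted p of 0.78 in edgeR. miR-132-3p (-0.06 ± 0.30) and miR-194-5p (0.00 ± 0.09) were near level. For miR-34c-3p, which rose in AM132 against AM608, AM608 itself lay below RCD in batch 2. It differed from RCD by -0.31 log2 CPM in AM608 and by 0.71 in AM132 (exact permutation p = 0.0444 and 0.0162, not adjusted). miR-375-3p averaged 2104 ± 5644 CPM in AM608 and 103.9 ± 3.1 in RCD (log2 fold change 4.34 ± 1.72), and only 3 of 8 AM608 libraries were above the RCD mean; AM608 5 stood at 14080.

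Each of the 17 lists had 0 calls in AM608 against RCD, over all miRNAs and adjusted over the list alone. The miR-17/92 clusters had 8 of 11 tested members lower (miR-20b-5p -0.52 ± 0.28, miR-106b-5p -0.22 ± 0.13; set p = 0.0161, adjusted p = 0.274 in camera), and the erythroid list all 5 (miR-451a -0.30 ± 0.32, miR-144-3p -0.25 ± 0.31; adjusted p = 0.562). The pituitary list had 8 of 9 higher (median 2.37, adjusted p = 0.754), but the median was -0.02 without the 3 libraries rich in miRNAs of other tissue, AM608 5 among them, and 0.01 with DESeq2. The choroid plexus list had 5 of 12 higher (miR-204-3p 0.15 ± 0.10, miR-34b-5p -0.26 ± 0.10), with a median of -0.03, a mean of 0.29 and a set test pointing down (adjusted p = 0.728). The Dlk1-Dio3 cluster had 23 of 45 higher (miR-369-5p 0.23 ± 0.09, miR-411-5p 0.12 ± 0.05), and the endothelial and mural list 6 of 7 lower (miR-126a-3p 0.10 ± 0.09, miR-145a-5p -0.25 ± 0.24). Without the 3 libraries rich in miRNAs of other tissue, miR-103-3p (energy balance and lipid lists, adjusted p = 0.036) and miR-23a-3p (oligodendrocyte list, adjusted p = 0.0397) fell, adjusted over the list alone in edgeR. Over all 589 miRNAs of that fit 0 passed (smallest adjusted p = 0.202 in edgeR), and the list values are not corrected over the 17 lists.

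Of 575 tRFs 0 passed in AM608 against RCD in edgeR and 28 had an unadjusted p under 0.05. DESeq2 called 1, tRF-32-P4R8YP9LON4V3, a 5'-half of GlyGCC with 571 ± 166 CPM in AM608 and 1216 ± 223 in RCD (SD, n = 8 and 4). Its edgeR log2 fold change was -1.09 ± 0.28 (adjusted p = 0.402, lower in 8 of 8 AM608 libraries), and its DESeq2 value was -1.21 ± 0.28 (adjusted p = 0.0096). The others of smallest p were tRF-36-UD10H7RNLEKPM4D of ThrAGT (0.91 ± 0.25), tRF-36-9LON4VN1EH6KK80 of GlyGCC (1.126 ± 0.318), tRF-33-PSQP4PW3FJI0W of LysCTT (-1.07 ± 0.35) and tRF-17-H7PU4HJ of SerAGA or SerTGA (0.81 ± 0.29). Further lysine fragments were the LysCTT 5'-halves tRF-33-PSQP4PW3FJI0V (-0.94 ± 0.39) and tRF-32-PSQP4PW3FJI01 (-0.74 ± 0.32) and the internal tRF-31-6XQ6S8V0J8O9E (-1.66 ± 0.71).

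As sets in AM608 against RCD with a preset correlation, 44 of the 51 5'-halves were lower (median -0.45, adjusted p = 4.23e-19) and so were glutamate fragments (median 0.00, mean -0.10, adjusted p = 0.0382). Internal fragments (median 0.13, adjusted p = 0.00118) and fragments of leucine (0.24, 0.00161), asparagine (0.34, 0.00519) and threonine (0.29, 0.034) tRNAs were higher. With an estimated correlation none held (adjusted p = 0.193 for the 5'-halves and 0.252 for threonine, the others 0.566 to 0.909). Scaling by RLE moved the median of all tRFs from 0.09 to -0.03; relative to it these sets kept their sign, but the internal fragments' own median was then 0.00.

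AM132 against RCD sets treated obese mice beside lean mice (batch 2, n = 8 and 4). Of 599 miRNAs 0 passed in edgeR, 59 had an unadjusted p under 0.05, and DESeq2 called 0. miR-34c-3p had the smallest p (0.83 ± 0.22; 51 ± 19.9 CPM in AM132 and 28.8 ± 2.67 in RCD; higher in 8 of 8 AM132 libraries; adjusted p = 0.488), and it was the 1 miRNA of any list that rose adjusted over the list alone (adjusted p = 0.015). It was followed by miR-101a-3p (0.15 ± 0.05), miR-7688-5p (0.67 ± 0.15), miR-101b-3p (0.14 ± 0.04) and miR-493-3p (0.63 ± 0.21), none past the test. miR-132-3p averaged 451 ± 174 CPM in AM132 and 785 ± 38.5 in RCD (-0.80 ± 0.29, lower in 8 of 8, adjusted p = 0.488). In log2 CPM it differed by -1.03 (exact permutation p = 0.0424), and without AM132 6 it was the 1 miRNA that passed (-0.64 ± 0.11, adjusted p = 0.00715). The other members of its cluster and of the miR-194 family did not pass, with miR-194-5p at -0.04 ± 0.09 and miR-192-5p at 0.23 ± 0.12.

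Among the other lists in AM132 against RCD, the let-7 family had 9 of 10 members higher (let-7a-5p 0.11 ± 0.06, miR-98-5p 0.09 ± 0.05; set p = 0.0195, adjusted p = 0.331 in camera, 0.998 with an estimated correlation). The muscle list had 3 of 3 higher and 0 calls (miR-1a-3p 1.06 ± 0.54, miR-133a-3p 1.25 ± 0.65), with AM132 6 far above the rest as given above; its median of 1.06 was 0.04 without AM132 6, -0.10 without the 3 libraries and 0.06 with DESeq2. The Hox-linked list also had 0 calls (miR-10a-5p 0.37 ± 0.21, miR-10b-5p 0.93 ± 0.54). Its median of 0.38 was 0.18 without AM132 6 and 0.16 without the 3 libraries. The energy-balance list held miR-200b-3p (4.23 ± 1.94; 6834 CPM in AM132 6) and miR-342-3p (-0.18 ± 0.08). The neuronal list held miR-129-1-3p (-0.28 ± 0.11) and miR-129-2-3p (-0.24 ± 0.11), the myeloid list miR-146b-5p (0.18 ± 0.08) and miR-150-5p (-0.13 ± 0.09), and the Dlk1-Dio3 cluster miR-667-3p (-0.24 ± 0.09) and miR-409-3p (0.29 ± 0.11); none passed. Without the 3 libraries rich in miRNAs of other tissue, miR-23a-3p of the oligodendrocyte list fell, adjusted over the list alone in edgeR (adjusted p = 0.0175). Over all 589 miRNAs of that fit only miR-132-3p passed, and the list value is not corrected over the lists.

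Of 575 tRFs 0 passed in AM132 against RCD in edgeR, 21 had an unadjusted p under 0.05, and DESeq2 called 0. The smallest p belonged to tRF-46-VIJMRPFQJDZXHY13KK0 of LysTTT (-0.68 ± 0.24), tRF-40-YDLBRY73W0K5KKOV of AsnGTT (0.68 ± 0.25), tRF-31-6XQ6S8V0J8O9E of LysCTT (-1.89 ± 0.71), tRF-50-8Y7Z2R1HPSR9O9337KB6 of GluTTC (1.96 ± 0.75) and tRF-36-UD10H7RNLEKPM4D of ThrAGT (0.63 ± 0.25), each with an adjusted p of 0.994 in edgeR. Other LysCTT fragments were tRF-31-6XQ6S8V0JUO9E (-1.71 ± 0.80) and tRF-46-PSQP4PW3FJIKE7UMKK0 (1.29 ± 0.66). As sets with a preset correlation, 5'-halves (median -0.12, adjusted p = 2.32e-05) and lysine fragments (-0.17, 0.011) were lower and the 5 arginine fragments (0.91, 0.029) higher; with an estimated correlation the adjusted p values were 0.712, 0.734 and 0.712. RLE scaling moved the median of all tRFs from 0.06 to -0.15, and these 3 sets kept their sign.

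The balance of the 2 RNA classes did not differ detectably. The log2 ratio of tRF to miRNA counts was -5.30 ± 0.54 in AM132 and -5.15 ± 0.51 in AM608 (SD, n = 16 each; difference -0.15, permutation within batch p = 0.336, adjusted over 3 comparisons 0.893). The difference was -0.45, -0.05 and -0.07 in batches 1, 2 and 3 (exact permutation p = 0.343, 0.812 and 0.771). Against RCD in batch 2 it was -0.09 for AM132 and -0.04 for AM608 (exact permutation p = 0.705 and 0.893).

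A test of treatment by batch asks whether AM132 acted differently in the 3 batches. It called 0 of 559 miRNAs (23 at an unadjusted p under 0.05) and 5 of 494 tRFs in edgeR. All 5 were long 5'-tRFs of LysCTT of 48 to 50 nt, among them tRF-50-PSQP4PW3FJIKE7UMKKSW, the most abundant tRF of the table with 13.7% of all counts. Its log2 fold change was -0.96 ± 1.16 in batch 1, 0.25 ± 0.52 in batch 2 and 7.69 ± 1.67 in batch 3. LysCTT fragments of 47 to 50 nt together ranged from 12 to 51300 counts per library. In batch 3 their log2 CPM was 15.17 ± 3.78 in AM132 and 8.16 ± 2.27 in AM608 (SD, n = 4 each; exact permutation p = 0.0571, adjusted over the 3 batches 0.171). The 5 calls ended without the 3 libraries rich in miRNAs of other tissue (0 passed, smallest adjusted p = 0.0603 in edgeR, against 0.0271 with them). All 3 are of batch 2, so every batch 3 library stayed in that fit.

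**Figure D3:**
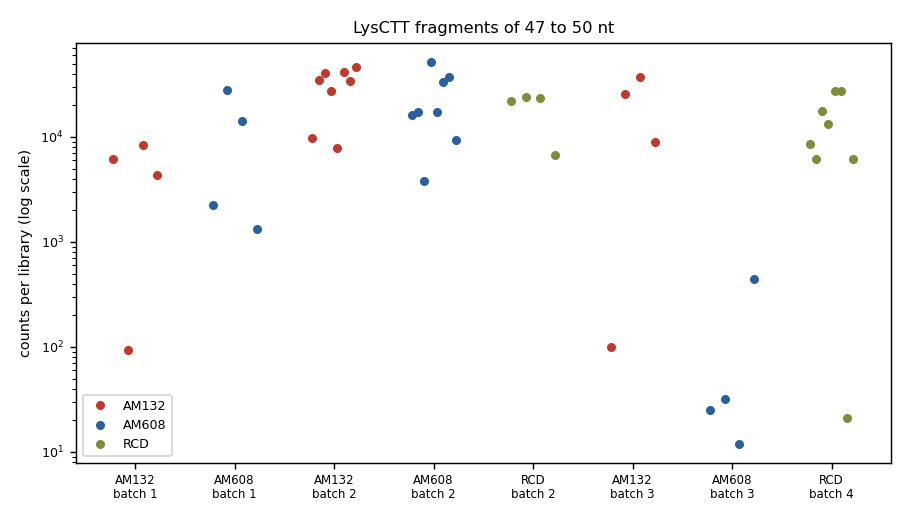
Each point is a library, placed by batch and group, with the summed counts of LysCTT fragments of 47 to 50 nt on a log axis. Batch 2 libraries lie between 3824 and 51300 counts, whereas batch 3 runs from 12 to 36958.

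Whether AM132 moved small RNAs toward their level in lean mice was tested across features, with no library shared: the AM132 minus AM608 fold changes of batches 1 and 3 were set against the RCD minus AM608 fold changes of batch 2. A negative correlation would mean a shift away from the lean level. Across 518 miRNAs Pearson's r was -0.30 and Spearman's rho -0.21. Exchanging treatment labels 100 times gave r between -0.28 and 0.27 (central 95%, permutation p for r = 0.06, adjusted over 2 relations 0.12). With 100 draws this range and p are coarse. For the 227 miRNAs with a mean of at least 100 CPM r was -0.43 (permutation p = 0.08). Across 470 tRFs r was -0.23 and rho -0.21 (permutation p for r = 0.29, adjusted 0.29). Features are not independent replicates, so these values carry no more weight than their label permutations give.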

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

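The tests on miR-132-3p, on AM132 6 and on the size range of the LysCTT fragments were chosen after the values were seen; the counts of splits and the scaling test were chosen before. Of 96 tests for a library far from the rest of its group and batch (Dixon's criterion), 10 passed, where chance gives about 1 in 20, or 4.8. The 5 tRFs below stood out by a difference between groups that varied with batch (adjusted p under 0.05).

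The first pattern is the lower miR-132-3p of AM132 in batch 2, where AM132 6 stood far below the others at 6.03 log2 CPM against 8.42 to 9.06. The tables argue against 1 library setting the difference, since without AM132 6 it was -0.613 (exact permutation p = 0.000311). They argue against dilution by RNA of other tissue, which would lower both arms of the hairpin alike, since the log2 ratio of the arms differed by -0.894, and by -0.577 without AM132 6 (exact permutation p = 0.000155). The treatment is the contrast tested and may account for the pattern. Masking of the miRNA during library preparation, which counts do not separate from its loss, stays open, and so does why batch 2 differed most, since the labels give the same dose and days for every treated library; neither was tested.

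The second pattern is AM132 6, which stood far from its group in 3 further lists: its mean log2(CPM + 1) was 7.66 for the choroid plexus and ciliated-cell list (5.38 to 6.28 in the other 7), 6.636 for the muscle list (3.77 to 4.20) and 3.591 for the Hox-linked list (2.60 to 3.04). It had 6874 CPM of miR-200a-3p, 5019 of miR-200c-3p and 2914 of miR-1a-3p, where the medians of the 40 libraries other than AM132 5, AM132 6, AM608 5 and RCD 7 were 53.3, 9.33 and 284.5. Its pituitary list mean was high too, at 10.25 (5.52 to 8.14 in the other 7), but 5 of the 9 members are of the miR-200 family, and pituitary tissue as the source of that excess is argued against, as the excess of miR-375-3p was 0.06 times that of miR-200c-3p (7.92 in AM608 5); a small share of pituitary stays open. A sample from another tissue altogether is also argued against, since the 18 neuronal list members deviated by a median of -0.0195. A mixture with epithelium or muscle stays open, stratified epithelium included, as 3 of 5 of its list members stood over 2 log2 units above the other 17 libraries of batch 2 (AM132 5 and AM608 5 left out), and no biological explanation was tested.

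The third pattern is the set of LysCTT 5'-tRFs whose AM132 effect differed between batches: tRF-48-PSQP4PW3FJIKE7UMKK0D (adjusted p = 0.0271 for treatment by batch in edgeR), tRF-49-PSQP4PW3FJI0E7UM8K2K (0.0425), tRF-50-PSQP4PW3FJIKE7UM8KSW (0.0425), tRF-50-PSQP4PW3FJIKE7UMKKSW (0.0425) and tRF-49-PSQP4PW3FJIKE7UMKK2K (0.049). A change in the size range or read length of whole libraries is argued against, as the SD of the other fragments of 47 to 50 nt over 44 libraries was 0.231 times that of the LysCTT ones (0.86 against 3.72 log2 units). A shift of the scaling by a few abundant fragments is argued against too, as 4 of these fragments passed with scaling over both tables. Of 100 splits within batches 3, the real one included, gave at least the 5 calls seen, and the highest other gave 13. This share was not adjusted over the split tests made. The 5 fragments also rose and fell together across libraries, so they are not 5 separate results, and chance is not excluded. Why another split gave 13 calls was not tested. RCD 7 had 21 counts of LysCTT fragments of 47 to 50 nt, AM132 2 had 94 and AM132 13 had 99. The fragments may thus vary with an unrecorded property of the samples, and that stays open.

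Other libraries stood apart as well, given as mean log2(CPM + 1). AM608 5 had 10.43 for the pituitary list (5.46 to 7.22 in its group and batch), with miR-375-3p at 14080 CPM, where AM132 5 had 944, AM132 6 had 515 and the other 41 libraries at most 193.6. AM132 3 had 4.839 for the muscle list (3.71 to 3.89) and 9.275 for the endothelial and mural list (8.46 to 8.60). RCD 7 had 5.208 for the muscle list (3.40 to 4.25), with miR-206-3p at 147 CPM. AM608 16 had 8.714 for the erythroid list (6.75 to 6.82). RCD 10 had 2.942 for the Hox-linked list (2.59 to 2.63).

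The libraries were also split into groups of the same sizes for the other counts. For the 2 miRNAs called between AM132 and AM608, 4 of 100 splits, the real one included, gave as many, and the highest other gave 7. This share was not adjusted over the split tests made, and the let-7b-3p call ended in several fits, so chance is not excluded. For the counts of 0 the splits decide nothing, since any split gives at least 0 calls. The highest count of another split was 2 for miRNAs in AM608 against RCD and 33 in AM132 against RCD. It was 22 for the miRNA test of treatment by batch. For tRFs it was 3, 0 and 2 in AM132 against AM608, AM608 against RCD and AM132 against RCD. Why single splits gave 33 and 22 calls was not tested.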

How the results depend on the processing

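Fits that leave out AM132 6, 3 libraries or long fragments were chosen only after the data were seen. No called result reversed. For miRNAs in AM132 against AM608 the 2 calls became 1 with no filter, in batch 2 alone, with TMM over both tables and without AM132 5, AM132 6 and AM608 5, each time miR-34c-3p, and 0 with no batch term, in batch 1 alone and in batch 3 alone. The miRNA count of 0 in AM608 against RCD became 2 (miR-1298-5p, miR-206-3p) with all 44 libraries and no batch term; in AM132 against RCD it became 3 (miR-10a-5p with both of these) there, where RCD 7 had 147 CPM of miR-206-3p and the other 43 libraries at most 15.07, and 1 (miR-132-3p) without AM132 6 and without the 3 libraries. For tRFs the 0 became 1 with DESeq2 in AM608 against RCD, 1 (tRF-31-6XQ6S8V0J8O9E) with no filter in AM132 against RCD, and 1 (tRF-31-PW5SVP9N15WV0) there with all 44 libraries and no batch term. Leaving out each RCD library of batch 2 gave 0 in every case. The 5 tRFs of the treatment by batch test became 4 with TMM over both tables, 4 without AM132 6, 6 without AM132 8, AM132 12 and AM608 8, 0 without the 3 libraries and 0 without fragments of 47 to 50 nt, which removes them. miR-132-3p differed by -0.175 in batch 1 alone and -0.2 in batch 3 alone, each with fewer samples and a smaller difference than batch 2 (-0.953). The correlation of treatment with diet (r) was -0.0892 with all batches for miRNAs (-0.30 before; rho 0.0838, -0.21 before) and 0.0531 for tRFs (-0.23 before), where shared AM608 libraries alone give 0.317 and 0.256, the means over exchanged labels (permutation p = 0.34 and 0.57). The tRF sets past camera's preset correlation (4, 6 and 3) became 0, 0 and 0 with an estimated correlation; fry, which tests a set against no change, gave 0, 0 and 0. The cause of the other shifts was not tested. Without fragments of 47 to 50 nt the median tRF fold change was -0.15 in AM608 against RCD and -0.18 in AM132 against RCD. With the replicate number as a block 2 miRNAs passed in AM132 against AM608, and 0 features in the other 5 comparisons; of 16 shared numbers 11 had a correlation above 0.1 in the miRNA table (median 0.201) and 7 in the tRF table, and 7 and 3 correlated best with their own; as pairing was to need all 16 above 0.1, the mice were not treated as paired, though some shared variation is not excluded. Of the values of named features, 1876 kept direction and side of the threshold, 6 gained a call, 9 lost one, and 88, without a call before or after, changed sign. At tRF depth, changes of 0.5 in the RCD comparisons were mostly below detection.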

Other observations

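miR-34c-3p differed more between batches than between treatments: it averaged 1.72, 5.40 and 2.00 log2 CPM in AM132 of batches 1, 2 and 3 (n = 4, 8 and 4), and 4.69 and 3.37 in RCD of batches 2 and 4 (n = 4 and 8). miR-204-5p, an abundant choroid plexus miRNA, ranked first in the miRNA test of treatment by batch (adjusted p = 0.273 in edgeR, not past the test), with a log2 fold change of -0.03 ± 0.11 in batch 1, -0.04 ± 0.05 in batch 2 and -0.52 ± 0.14 in batch 3.

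The following test was chosen only after the results were seen. The hypothesis was that the oligonucleotide may lower further miRNAs through sequence shared with its target. Among the 95.3% of tested miRNAs whose hairpin was in the annotation, 20 have a hairpin arm that shares at least 7 bases in a row with miR-132-3p. Their mean log2 fold change of 0.07 (median 0.00) stood at percentile 84.33 of 10000 random lists matched for abundance. That mean rests on miR-34c-3p, which rose, and miR-183-5p (0.69); the other 18 averaged -0.01. Other lengths were computed too: 69 miRNAs with at least 6 bases had a mean of 0.04 (percentile 78.52), and the 7 with at least 8 bases a mean of -0.05 (percentile 3.59; 12.56 with the fold changes of batch 2), so lowering through shared sequence stays open.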
